A study of Homo sapiens with 8 samples.

How the data were processed

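The files hold 8 droplet libraries of T47D cells, 4 of the parental line and 4 of primed cells, made with 10x 3′ chemistry and 10000 cells targeted per sample, per the submitters' processing notes. Those notes name Cell Ranger 7.2.0 with the hg38 genome, R 4.4.0 and Seurat 5.1.0. The deposited values are raw UMI counts, whole numbers over 62700 genes, for barcodes with 500 UMIs or more. No cell types, clusters or cell lists were used from the study, so any difference from its own cell groups may come from names rebuilt here. The labels call the cell type goblet cells and give the line another catalogue number than the one expected for T47D; the comparison here uses the group labels alone.

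Barcodes were compared among libraries before any sum. Because the 4 libraries of a group shared nearly all barcodes with proportional totals, the counts of each barcode were added over them, giving 12964 parental barcodes (12687 of them in all 4 libraries) and 16742 primed ones (14180). Barcodes with under 1000 detected genes (403 parental and 2530 primed) or over 20% mitochondrial UMIs (1907 and 1256) were left out, and 10860 and 13348 cells were kept. Scrublet marked 1 cell per group, which means that it did not work, so doublets were not removed and no alternative without doublets was run. Per-cell measures used cells thinned to 5000 UMIs, which 10682 parental and 12240 primed cells allowed; the shallower cells were left out of them.

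The plan written before the data were examined treated each library as a replicate and named the edgeR quasi-likelihood test, camera and fry for gene lists and chromosomes, DESeq2, a replicate block and exact permutation tests of library shares. With 1 capture per group none of these has a spread to work with, and none was run. In their place counts were summed over the cells of each capture, scaled with TMM factors (edgeR 4.0.16, limma 3.58.1, R 4.3.3, over genes kept by filterByExpr with a minimum count of 10), and given as CPM and log2 ratios for genes with a mean CPM of at least 1. The factors differ a little between comparisons, and with them the parental CPM. A sum of 0 over a group was set to a floor of 3 counts. Intervals at 95% are exact binomial ones for shares and exact conditional ones for ratios of counts, the latter on counts divided by 4, since a molecule may be counted in each of 4 libraries, and they cover counting error only. A list or chromosome value is the median log2 ratio of its members, set against 10000 random lists or 2000 random sets drawn from 20 bins of expression, with at least 5 genes in a list and 50 on a chromosome. The 35 gene lists were fixed before the data were examined. Gene positions came from GENCODE release 29 (hg38) for 58207 genes.

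Cells of each group, 8000 drawn with a fixed seed, were clustered apart from the other group (scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2): thinned counts, log-normalized, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5, which gave 7 parental and 10 primed clusters. A cluster was named from fixed marker lists when at least 3 markers of 1 list were among its 10 leading genes by fold. The terms VIM-high, mixed and side group are descriptive and were chosen after the values were seen. Of the primed clusters with high VIM, those with PRLR at over 10 times the median of the clusters were called mixed and the rest VIM-high. Luminal-like and VIM-high cells were summed and compared with all parental cells in the same way. Phases were called with the scanpy cell cycle score on both groups together. The score of primed likeness took 100 genes per direction with a mean CPM of at least 50 from one random part of the cells, in place of replicates 1 and 2 as planned, and was read in the other part.

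Named genes followed a rule fixed in advance, with the parts that asked for an adjusted p left out: a panel of 15 genes; the 12 genes with the largest positive and the 12 with the largest negative log2 ratio at a mean CPM of at least 10, leaving out clone names; and for each list, among members at a mean CPM of at least 5, the 3 with the largest ratio in the direction of most members and the 1 with the largest opposite ratio. This gave 154 genes for the primed capture, 152 for luminal-like and 157 for VIM-high cells. MTAP and CDKN2A were chosen before their own values were seen, but after the profile of the primed cells and the lower level of their neighbour CDKN2B in the primed capture. The other genes of the regions on chromosomes 9 and 12, the leading genes of the clusters, SPANXB1 as the measure of carried-over RNA and CD44 were chosen after their values were seen. Genes of the Y chromosome and XIST are not reported, nor are a few genes of the rule that are withheld.

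Alternatives changed 1 choice at a time. As exceptions, all deposited barcodes and the stricter filter on cells changed the gene minimum and the mitochondrial maximum together. For cells these were all deposited barcodes, at least 2000 genes and under 10% mitochondrial UMIs, G1 cells only, barcodes found in both groups left out, and equal depth. For genes they were RLE factors, mitochondrial and ribosomal genes left out, no gene filter, a mean CPM of at least 10, genes above the median mean expression. For shares and scores they were thinning to 2500 UMIs or none, phase calls by a median plus 2 MAD, 50 score genes per direction and the 1st and 10th percentile, both parts of the cells exchanged. For clusters they were Leiden resolutions of 0.3 and 1, clusters without cycle genes. Each library was left out in turn. For luminal-like cells there were also the parental side group as reference, cells with under 0.5 VIM UMIs per 1000, and the VIM-high profile subtracted at the SPANXB1 share. Windows of 50 neighbouring genes with a mean CPM of at least 5 were used along chromosomes, with 200 shuffles of their order. The procedure was tested on simulated counts over 15227 genes. The other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.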

Results

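The series holds 8 single-cell RNA libraries of T47D, an established line of luminal, estrogen receptor positive breast cancer cells: 4 of parental cells with no treatment and 4 of primed cells, taken 6 months after estradiol depletion. The question is how the cells labelled primed differ from those labelled parental. The parental libraries held 12773, 12912, 12730 and 12810 barcodes with 131332957, 145987981, 125559376 and 138607296 UMIs. The primed libraries held 15048, 14452, 16460 and 14722 barcodes with 126742899, 110711359, 157720519 and 117417648 UMIs. Median UMIs per barcode were 9028, 9973, 8646 and 9519 in parental and 7443, 6720, 8600.5 and 7017 in primed libraries, and mitochondrial genes took 15.8% of the UMIs of parental replicate 1 and 10.6% of those of primed replicate 1.

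The 4 libraries of a group carried the same cells. Any pair of libraries of 1 group shared 98.5 to 99.8% of the barcodes of the smaller one, with a correlation of UMI totals over barcodes of 0.9996 to 0.9998. Where a gene had 2 UMIs in a cell over a pair of libraries, the UMIs lay 1 in each in 53.5 to 56.1% of cases, against 48.5 to 49.97% from the depths alone. The counts of each barcode were therefore added over the 4 libraries, which left 1 capture per group: 10860 parental cells with 487900593 UMIs and a median of 39357.5 per cell, and 13348 primed cells with 486022704 UMIs and a median of 31936.5. There is no replicate check on any difference between the groups, no test was made, and every interval below is a 95% interval that covers counting error only.

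Most cells of the primed capture had a profile far from that of the parental cells, and a minority had a luminal profile. VIM, an intermediate filament gene of mesenchymal cells, stood at 2.11 CPM in parental and 3951 CPM in primed cells, and SPANXB1, a cancer-testis gene on the X chromosome, at 0.317 and 877 CPM. In the parental clusters, whose cells had 5000 UMIs or more, VIM stood at 0.190 to 0.734 CPM. The pooled parental value also holds shallower cells, so such low parental levels and the ratios over them are rough. After thinning to 5000 UMIs, all 10682 parental cells had 5 or fewer VIM UMIs (100%, interval 99.97 to 100), while 1442 of 12240 primed cells did (11.8%, 11.2 to 12.4). Of 8000 clustered primed cells, 811 (10.1%, 9.48 to 10.8) formed a luminal-like cluster led by GHR, ESR1, ERBB4, TMTC1, GRHL2, NCAM2, PGR, PRLR, S100A9 and UNC5C, of which ESR1, GRHL2 and PRLR are luminal markers fixed in advance and S100A9 is an inflammatory gene. Another 6544 cells in 8 clusters (81.8%, 80.9 to 82.6), called VIM-high here, matched no list of a tissue cell type. Among these clusters, cluster 10 (161 cells) had 7 interferon response genes among its 10 leading genes. A further 645 cells (8.06%, 7.48 to 8.68) lay between luminal-like and VIM-high cells in 1 cluster called mixed. Median UMIs per cell were 38177, 31954.5 and 57078 in luminal-like, VIM-high and mixed cells, and mitochondrial shares 15.6, 8.49 and 10.96%. The 20% mitochondrial maximum set part of the makeup: among the primed barcodes it removed, 74.0% (71.1 to 76.7) had 5 or fewer VIM UMIs, and without it the share over all primed barcodes of that depth was 16.3%.

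**Figure D1:**
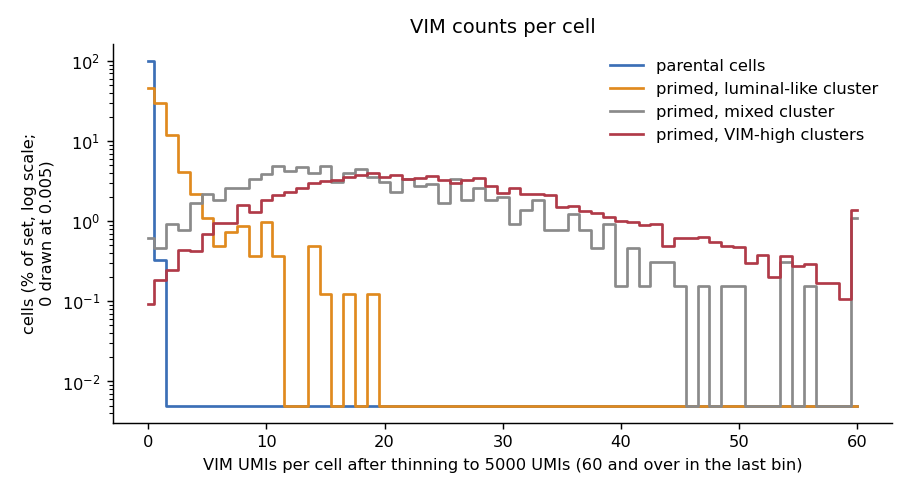
Percent of cells (log axis) by VIM UMIs per cell after thinning to 5000 UMIs, for parental cells and for the luminal-like, mixed and VIM-high clusters of primed cells. All 10682 parental cells lie at 5 UMIs or fewer, as do 95.3% of luminal-like and 2.09% of VIM-high cells.

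In the primed capture as a whole, the estrogen receptor programme and the luminal identity genes were lower than in parental cells. Of 34 estrogen receptor targets compared, 27 were at least 2-fold lower and 2 at least 2-fold higher (median log2 ratio -2.52). GREB1, a coactivator of the receptor, went from 252 to 8.22 CPM (log2 ratio -4.94) and TFF1, a secreted trefoil peptide, from 122 to 5.11 CPM (-4.57). PDZK1 went from 44.2 to 1.62 CPM (-4.77), PGR, the progesterone receptor, from 568 to 28.2 CPM (-4.33) and MYB from 17.1 to 1.53 CPM (-3.49). Of 24 luminal identity genes, 20 were at least 2-fold lower and 1 higher (median -2.41). Among them were ESR1 itself (900.5 to 80.2 CPM, -3.49), GATA3 (736 to 119 CPM, -2.63), and FOXA1, the pioneer factor that opens receptor sites (131 to 9.75 CPM, -3.75). The prolactin receptor PRLR (2519 to 147 CPM, -4.09) was lower too. KRT7, a simple epithelial keratin, was the exception named by the rule (1.47). CCND1, a receptor target that drives entry into the cycle, was also higher (199 to 431 CPM, 1.12). Among the largest negative log2 ratios were those of the secreted matrix protein MGP (7488 to 17.8 CPM, -8.72), IGFBP5 (598 to 2.30 CPM, -8.02), PREX1 (234 to 1.15 CPM, -7.67) and STC2 (552 to 3.98 CPM, -7.12).

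Mesenchymal, inflammatory and interferon genes were higher in the primed capture. Of 16 genes of the epithelial-mesenchymal transition, 15 were at least 2-fold higher and none lower (median 6.16), with the metalloprotease MMP14 at a log2 ratio of 10.15. Of 25 NF-kB and inflammatory genes, 24 were higher (median 5.24), including the chemokine CXCL8 (10.92), the acute phase gene SAA2 (11.08) and the cytokine IL6 (10.29). Of 33 interferon response genes, 25 were higher (median 2.14), with IFI44 at 8.99 and IFIT3 at 8.11, while BST2 was lower (-0.53). Of 19 genes of MHC class I presentation, 8 were higher (median 0.81). Immediate early genes had 16 of 21 higher (median 2.45, FOSL1 9.65). YAP and TEAD targets had 10 of 19 higher and 3 lower (median 1.54, ANKRD1 9.65, AXL 9.38). Basal epithelium had 8 of 13 higher and 1 lower (median 1.47, LAMB3 6.96). Receptor tyrosine kinases had 11 of 22 higher and 8 lower (median 0.81, ROR1 8.94 and FGFR2 -6.25). Quiescence and cell cycle inhibitors had 13 of 23 higher and 2 lower (median 1.28, CDKN1C 7.40, CDKN1A 1.79). Hypoxia and glycolysis had 14 of 28 higher and 1 lower (median 1.03), and the unfolded protein response 3 of 20 higher and 1 lower (median 0.55). The cystatin genes CST1 (12.06) and CST4 (11.99) and the protease PRSS2 (12.98) had the largest positive log2 ratios.

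Genes of respiration were lower in the primed capture and chromatin regulators were near the level of all genes. Of 50 nuclear genes of oxidative phosphorylation 20 were at least 2-fold lower and none higher (median -0.86, NDUFB9 -2.23), and of 13 mitochondrially encoded genes 6 were lower (median -0.81, MT-ND5 -1.53). The list of goblet cell markers, taken because the labels give that cell type, had 5 of 6 genes lower (median -3.01, or 0.35 without the gene filter, TFF3 1447 to 70.5 CPM). For CTCF and cohesin, which fold chromatin into loops, 2 of 16 genes were lower and 1 higher (median -0.16), with CTCF at 88.8 and 64.0 CPM (-0.47, -0.52 to -0.43). Polycomb genes had 6 of 32 higher and none lower (median 0.14, EZH2 0.29, PHC2 2.22), and SWI/SNF complexes 2 of 24 higher and 3 lower (median -0.0022). Histone and DNA modifying enzymes had 7 of 63 higher and 4 lower (median -0.06, HDAC9 2.91, KDM7A -2.35) and linker and replacement histones 5 of 18 lower and none higher (median -0.27, H1-5 -3.78). The lists for androgen and progesterone response (median -0.38), cholesterol synthesis and uptake (-0.04), fatty acid synthesis (0.22), cytosolic ribosomal proteins (-0.22), integrated stress response (-0.17), p53 targets (-0.38), WNT and NOTCH (-0.15) and endometrial epithelium (-0.62) lay within the central 95% of random lists of matched expression, and autophagy and lysosome (0.39) lay above it. Fibroblast, endothelium and leukocyte markers had 4, 3 and 1 genes at 1 CPM or more in this comparison, too few for a list value.

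Over all genes, 16483 were compared between the captures, of which 3298 were at least 2-fold higher and 3359 at least 2-fold lower in primed cells, and 59.6% lay within 2-fold. These counts depend on the gene filter, and the values above mix both kinds of primed cell, so the luminal-like and the VIM-high cells were each set against parental cells, a comparison added after the data were seen.

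**Figure D2:**
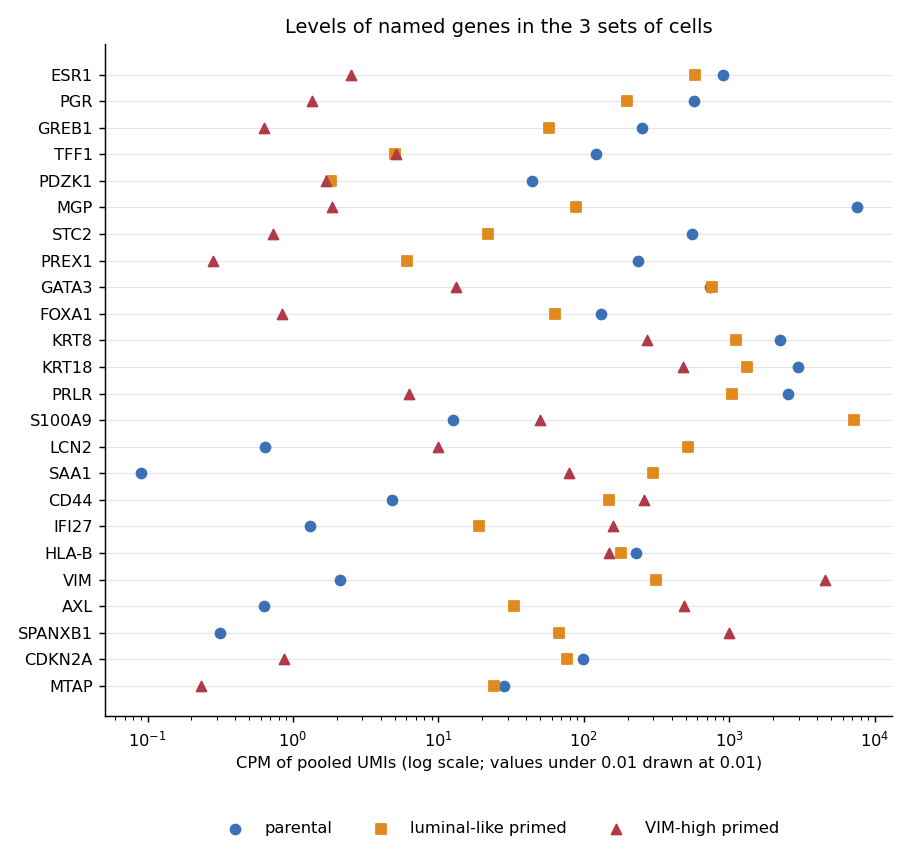
Level in CPM (log axis) of luminal, estrogen receptor target, inflammatory and mesenchymal genes in parental, luminal-like primed and VIM-high primed cells, 1 capture per group, summed over cells. ESR1 stands at 900.5, 576 and 2.51 CPM, VIM at 2.11, 312 and 4519 CPM and S100A9 at 12.7, 7172 and 50.1 CPM.

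The luminal-like primed cells held luminal transcripts, had lower estrogen receptor targets and had higher inflammatory and interferon genes. Their cluster was named by luminal identity genes (ESR1, GRHL2 and PRLR) that led it among primed cells. Holding luminal transcripts was thus part of its definition, while their level against parental cells was not. Of 25 luminal identity genes, 3 were at least 2-fold lower and 2 higher (median log2 ratio 0.08), with GATA3 at 708 and 754 CPM (0.09, 0.05 to 0.13). Members went both ways: KRT8 (-0.96), KRT18 (-1.11), KRT19 (-0.92) and PRLR (-1.23) were lower, and the CPM of the list added up to 17560 in parental and 11990 in luminal-like cells. ESR1 stood at 867 and 576 CPM (-0.59, -0.63 to -0.55), and the log2 ratio of FOXA1 was -0.99. Of 34 estrogen receptor targets, 18 were at least 2-fold lower and 2 higher (median -1.03), below all of the random lists. PDZK1 (-4.53, -5.31 to -3.85), TFF1 (-4.53, -4.97 to -4.11), GREB1 (-2.08, -2.21 to -1.96), PGR (-1.47, -1.53 to -1.40) and MYB (-1.44, -1.86 to -1.06) were lower. TSKU was higher (1.27), and CCND1 stood at 191 and 178 CPM (-0.11). Against the parental side group described with the chromosomes, the luminal identity median was -0.17, GATA3 stood at -0.07 and CCND1 at 0.061. MGP (7206 to 88.3 CPM, -6.35) and IGFBP5 (575 to 7.30 CPM, -6.30) were lower here too. Of 22 NF-kB and inflammatory genes 21 were higher (median 5.96), among them SAA1 (11.74), SAA2 (12.43), CCL20 (10.79) and LCN2, an iron-binding defence protein (0.622 to 515 CPM, 9.69). The calgranulins S100A8 (1.91 to 2085 CPM, 10.09) and S100A9 (12.2 to 7172 CPM, 9.20), the acute phase proteins ORM1 (11.78) and LBP (10.55), complement factor CFB (10.04) and S100A7 (13.68) were higher too. Of 30 interferon response genes 21 were higher and none lower (median 1.79, IFITM3 5.04, IFI27 3.90, ISG15 3.69), and of 19 genes of MHC class I presentation 7 were higher (median 0.70, PSMB9 2.51).

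RNA of the VIM-high cells was present among these values. SPANXB1, AXL and VIM stood in luminal-like cells at 6.78, 6.79 and 6.91% of their VIM-high level, while S100A9 stood at 14323% and CD44 at 57.0%. The list for the epithelial-mesenchymal transition had 11 of 12 genes higher (median 3.01, or 1.62 with a 6.78% share of the VIM-high profile subtracted and 3.87 in low-VIM cells only). Immediate early genes had 12 of 21 higher (median 1.201, or 0.50 subtracted and 0.87 in low-VIM cells), basal epithelium 5 of 10 higher and 1 lower (0.70, or -0.14 and 0.30) and hypoxia and glycolysis 7 of 27 higher and 2 lower (0.20, or -0.046 and 0.11).

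Among the other lists in luminal-like cells, those of G2 and M phase (median -0.59, 4 of 54 lower, or 0.048 in G1 cells only and -0.25 against the parental side group), nuclear oxidative phosphorylation (-0.55, 3 of 50 lower, or -0.35 against the side group), integrated stress response (-0.42, 4 of 20 lower and 3 higher), linker and replacement histones (-0.36) and goblet cell markers (-1.94, 4 of 6 lower) lay below the central 95% of random lists. Quiescence and cell cycle inhibitors (0.50, 7 of 22 higher, BTG2 3.03, or 0.30 with the VIM-high profile subtracted) and receptor tyrosine kinases (0.26, 9 of 21 higher and 2 lower) lay above it. So did Polycomb complexes (0.21, 0 of 32 at least 2-fold higher), histone and DNA modifying enzymes (0.13, 0 of 63 higher and 2 lower), mitochondrially encoded genes (0.29, 0 of 13 higher, or -0.12 with clusters at resolution 0.3) and cytosolic ribosomal proteins (0.10, 0 of 76 higher). CTCF and cohesin (0.06), SWI/SNF complexes (0.17), S phase (-0.07), cholesterol synthesis (0.14), fatty acid synthesis (0.19), unfolded protein response (0.03), p53 targets (-0.07), YAP and TEAD targets (0.16, or -0.066 with the VIM-high profile subtracted), WNT and NOTCH (0.24), autophagy (-0.13) and androgen and progesterone response (-0.32) lay within it. In all, 15688 genes were compared, 1489 were at least 2-fold higher, 1369 at least 2-fold lower and 81.8% within 2-fold.

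The VIM-high cells had few transcripts of ESR1, PGR, GREB1 and PRLR and lacked those of a stretch of the short arm of chromosome 9. ESR1 stood at 2.51, PGR at 1.36, GREB1 at 0.634 and PRLR at 6.26 CPM. In these cells 22 of 24 luminal identity genes (median -4.34) and 28 of 34 estrogen receptor targets (-3.67) were at least 2-fold lower than in parental cells. The keratins KRT8, KRT18 and KRT19 were lower but present: KRT8 went from 2271 to 273, KRT18 from 2987 to 481 and KRT19 from 3778 to 546 CPM. After thinning, KRT8 was seen in 70.6% of VIM-high cells. Between FOCAD and TUSC1 on chromosome 9, HACD4 (6.62 to 0.0464 CPM), KLHL9 (20.3 to 0.147 CPM), MTAP (28.5 to 0.232 CPM, positions 21802543 to 21937651 in hg38), the tumour suppressor CDKN2A (100.5 to 0.866 CPM, positions 21967753 to 21995301), CDKN2B (4.46 to 0.0232 CPM) and LINC01239 (33.4 to 0.0967 CPM) stood at under 1% of the parental level, and CDKN2B-AS1 at 9.18%. The neighbours FOCAD (59.9 to 48.7 CPM) and TUSC1 (13.05 to 10.7 CPM) did not. In luminal-like cells MTAP stood at 24.2 and CDKN2A at 76.9 CPM. These genes were looked at because other breast cancer lines have lost them, not under the rule for named genes. Of 16 genes of the epithelial-mesenchymal transition 15 were higher (median 6.31), of 24 NF-kB and inflammatory genes 22 (4.63), of 33 interferon genes 25 (2.17) and of 19 YAP and TEAD targets 10 (1.62), and TWIST1 was lower (-3.75). Among other cell type lists, of 15 basal epithelium genes 10 were higher and 2 lower (2.07). The 5 fibroblast genes were split, with 3 higher and 2 lower (6.32), and their summed level went from 82.0 down to 58.5 CPM. Over 16525 genes, 3571 were at least 2-fold higher and 3909 at least 2-fold lower.

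**Figure D3:**
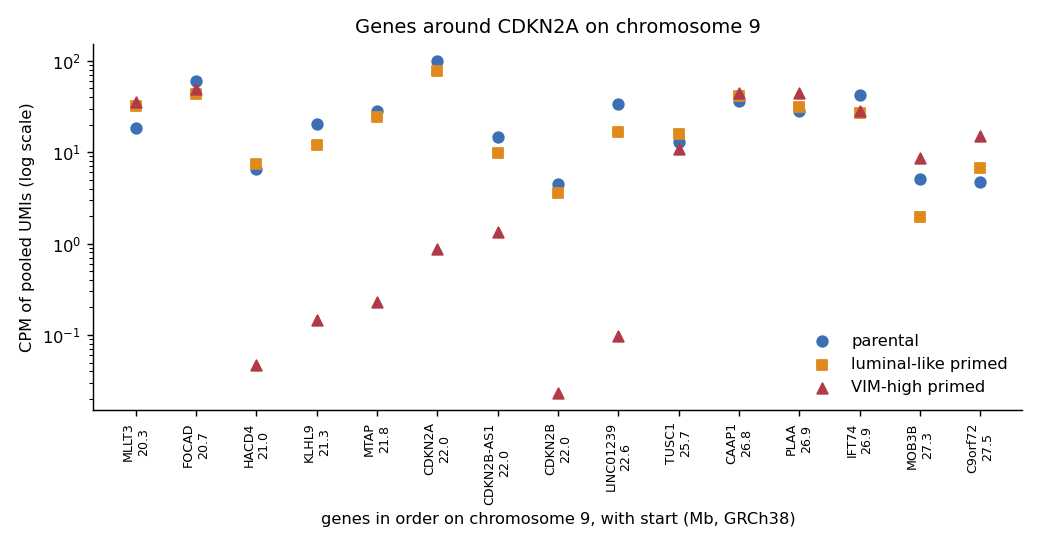
Level in CPM (log axis) of genes from MLLT3 to C9orf72 on chromosome 9, in their order and with their start in megabases (hg38), in parental, luminal-like primed and VIM-high primed cells. From HACD4 to LINC01239 the VIM-high cells lie at 0.290 to 9.18% of the parental level and the luminal-like cells at 53.1 to 117%.

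Expression also differed by chromosome, over part of its length on several of them. Over the autosomes, the median log2 ratio of VIM-high to parental cells was -0.83 over 705 genes of chromosome 16, -0.72 over chromosome 21, -0.51 over chromosome 8 and -0.47 over chromosome 11, and 0.41 over chromosome 2, 0.35 over chromosome 6 and 0.33 over chromosome 4. In luminal-like cells it was -0.44 over chromosome 15, -0.42 over chromosome 5 and -0.14 over chromosome 20, and 0.20 over chromosome 14 and 0.16 over chromosome 12. A median can hide opposite parts: on chromosome 11 the windows of VIM-high cells up to position 31790328 stood at 0.40 to 0.61, and on chromosome 5 the first window of luminal-like cells, up to 32313009, stood at -0.02. Within the parental capture, clusters 3 and 4 (1943 of 8000 cells, 24.3%, 23.4 to 25.2), called the side group, were set apart by their balance of chromosomes 12 and 14 against 15 and 20q, with a median log2 score of 1.36 against 0.58 in the other clusters. The score was over 1.2 in 784 of 811 luminal-like cells (96.7%, 95.2 to 97.8), in 20.3% of all parental cells and in 9.001% of VIM-high cells, and a cluster entered the side group at a median over 1, a bound set after the scores were seen. Of the chromosomes with at least 50 genes, 17 lay outside the central 95% of random gene sets of matched expression in VIM-high cells, 14 in luminal-like cells and 14 in the whole primed capture, where the medians were, among autosomes, -0.71 over chromosome 16 and 0.36 over chromosome 2.

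**Figure D4:**
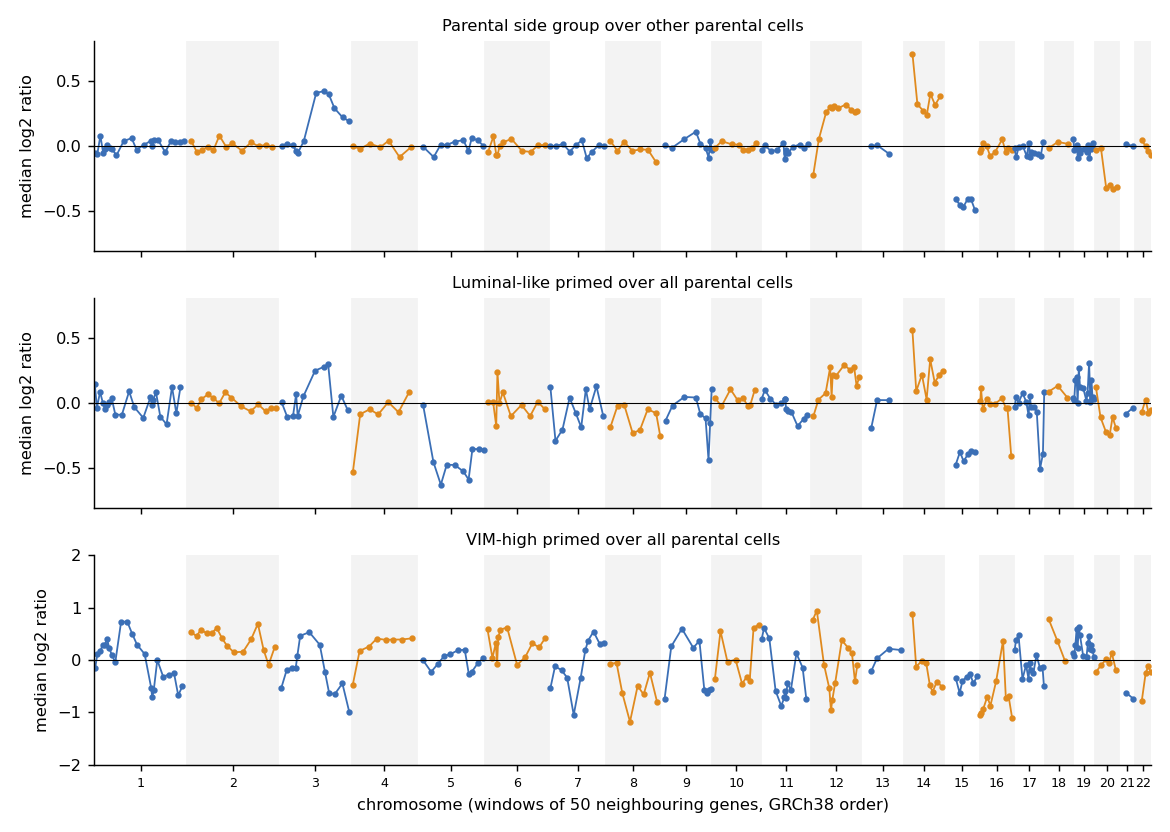
Median log2 ratio to parental cells in windows of 50 neighbouring genes along the chromosomes, for VIM-high and luminal-like primed cells, and of the parental side group over the other parental cells. Both the luminal-like cells and the side group have shifts on chromosomes 12, 14, 15 and 20, by which the side group was picked. Against a separate part of the other parental cells, the chromosome 15 median of the VIM-high cells is -0.45 too.

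**Figure D5:**
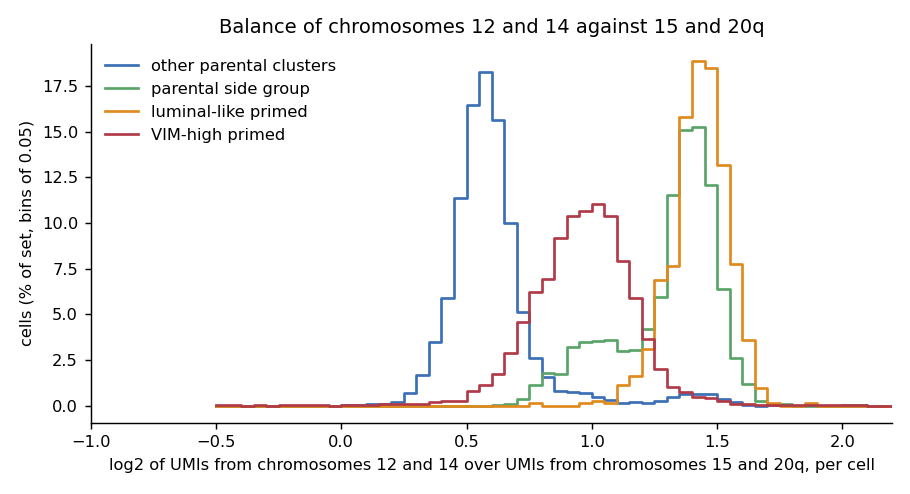
Percent of cells in each set (bins of 0.05) by the log2 ratio of UMIs from chromosomes 12 and 14 over UMIs from chromosomes 15 and 20q in each cell. The other parental clusters center at 0.58, VIM-high cells at 0.97, the parental side group at 1.36 and luminal-like primed cells at 1.43.

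Fewer primed than parental cells held transcripts of the receptor and its targets. After thinning to 5000 UMIs, ESR1 was seen in 89.7% of parental, 11.5% of primed, 81.1% of luminal-like and 1.48% of VIM-high cells (99.5, 20.8, 98.5 and 7.24% unthinned). In the same order PGR was seen in 74.9, 5.66, 40.1 and 0.611% (97.6, 14.9, 77.3 and 4.202% unthinned), and GREB1 in 61.6, 2.75, 20.2 and 0.336% (96.3, 10.7, 65.5 and 2.09% unthinned). TFF1 was seen in 24.3% of parental and 1.73% of luminal-like cells (56.3 and 6.41% unthinned) and PDZK1 in 15.5 and 0.617% (47.3 and 7.52%). Over 39 leukocyte, endothelial and fibroblast markers the median share was 0.0187% in parental, 0.172% in primed and 0% in luminal-like cells, with single markers at up to 22.8% (ACTA2, parental) and 18.4% (ESAM, primed). This does not measure RNA carried between the cell kinds: VIM was seen in 53.9% and SPANXB1 in 19.2% of luminal-like cells. Of 13 panel genes 9 had a lower share in primed than in parental cells. CCND1 (55.3 and 79.1%), MKI67 (32.7 and 45.8%), TOP2A (42.9 and 53.3%) and CDKN1A (4.10 and 14.1%) had a higher one.

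By phase calls, 24.6% of parental (23.8 to 25.4), 14.1% of primed (13.5 to 14.8), 27.1% of luminal-like (24.1 to 30.3) and 13.5% of VIM-high cells were in S phase, and 37.7, 51.1, 29.7 and 51.6% in G2 or M. The list medians went the same way in the primed capture, with S phase genes at -0.50 (8 of 43 lower and 3 higher) and G2 and M genes at 0.22 (4 of 54 higher and 2 lower), and MKI67 stood at 150 and 223 CPM (0.57). The calls also read free RNA, which was not separated here, and a different rule for calling phases moved the G2 and M difference from 13.4 to 2.99 points.

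Parental cells were also scored for likeness to primed ones. On a score of 100 higher minus 100 lower genes, chosen in one random part of the cells of each group and read in the other, 6 of 5341 parental cells (0.112%, 0.0412 to 0.244) lay above the 5th percentile of primed cells. With both parts exchanged 12 cells did (0.225%), and 65 (1.22%) lay above the 1st percentile. Both parts come from the same captures, so this is no independent check. The bound lay among the luminal-like cells, where RNA of the VIM-high cells is present. Such RNA may take part in setting the bound, which was not tested. Of 200 clustered primed cells under that percentile 199 were luminal-like, and the median score was -1.01 in parental, -0.43 in luminal-like and 0.87 in VIM-high cells.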

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

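In this part the test for doublets and the subtraction of the VIM-high profile were chosen after the result was seen, and the bounds of the other tests were written before the values they judge. By then the profile of the primed cells, their lower level of CDKN2B (a neighbour of MTAP and CDKN2A) and the levels of SPANXB1 had been seen, so none of these tests was blind to the data. Among 38 sets of 4 libraries (depths, mitochondrial shares and panel genes), 0 held a library far from the others. The libraries of a group carry the same cells, so this says nothing about separate samples.

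A signal lay in barcodes that the comparisons do not treat on their own. Of the barcodes, 562 occurred in both groups, 239 of them kept as cells in both, and the log10 UMI totals of the 2 sides correlated at -0.888 over barcodes. In 231 of them the parental side had over 10 times fewer UMIs (median 1094), and it held VIM at 2993 CPM and KRT8 at 480 CPM, against 3145 CPM of VIM on the primed side (median 118428 UMIs) and 2.00 CPM in all kept parental cells. In 269 the primed side was the smaller one (median 1061 UMIs), with PRLR at 2404 CPM against 2841 CPM on the parental side. VIM stood there at 553 CPM, against 0.141 CPM on the parental side and 4154 CPM in all kept primed cells, so these sides did not simply follow the other group. Leaving out all barcodes found in both groups gave 3310 genes higher and 3367 lower in primed cells, against 3298 and 3359.

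The VIM-high cells made up 81.8% of clustered primed cells, with VIM at 4519 CPM and ESR1 at 2.51 CPM. MTAP stood at 0.814% of the parental level. The 5% bound written before would count this against a change of state of the parental line without a change of genome. A missing transcript cannot tell a lost from a silenced gene, so this does not settle it. PRLR stood at 0.604% of the luminal-like level in cells of no higher median UMI count. Clusters with high VIM and high PRLR had been named mixed, so a low PRLR was built into the VIM-high set. It therefore cannot exclude doublets or free RNA. The mixed cells (VIM at 3671 and PRLR at 257 CPM, median 57078 UMIs) were not tested for doublets. Cells of another genome than the parental line are a candidate explanation, with no DNA measured. CDKN2A stood at 0.862% of the parental level, and log2 ratios of neighbouring windows of 50 genes correlated at 0.674 (-0.137 to 0.132 with shuffled order). The test along chromosomes had asked for a correlation at least 0.2 above that of the luminal-like cells, which was not met because these carry chromosome shifts of their own (0.627, against 0.0605 between 2 parts of the other parental cells), so that part of it separates nothing and the explanation rests on the chromosome 9 genes. Whether such cells silenced these genes, arose from T47D by loss of DNA or came from elsewhere stays open. So does what the depletion did, since it is confounded with the 2 captures.

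Genes higher in the luminal-like primed cells than in parental cells numbered 1489. If free RNA from the VIM-high cells were the whole source, they would stand near the SPANXB1 share of 6.78% of the VIM-high level, and 71.3% of them (1061) stood at over 3 times that share. For the 352 genes (23.6%) within 2-fold of the share, VIM and AXL among them, free RNA or a few VIM-high cells in the cluster stay open. The medians of the NF-kB and inflammatory list (5.96) and the interferon list (1.79) became 5.24 and 1.71 with the VIM-high profile subtracted, and that of the estrogen receptor targets went from -1.03 to -1.003. The inflammatory and interferon profile and the lower receptor targets may therefore belong to the luminal-like cells themselves, as a hypothesis, with the depletion and the presence of other cells beside them both untested as its source.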

How the results depend on the processing

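The alternatives on free RNA, on the reference and on clusters for luminal-like cells, the mean CPM of at least 10, the barcodes in both groups and all alternatives for luminal-like and VIM-high cells were chosen after the data were seen. Over 20 comparison results and 271 alternatives, 244 values stayed within their bounds and 27 moved. The bound for counts of genes and lists was a wide one, set as a ratio to the main value. The 1489 genes higher in luminal-like cells became 2083 at resolution 0.3 and 1156 with free RNA subtracted, and both were read as staying. The alternatives include each library left out in turn, which keeps the same cells, so the tally is no measure of robustness. Among these results only the S phase and the G2 and M differences could be read as reversed, and 0 were. The others could only stay or move. Over 572 single genes, lists and shares and 10339 alternatives, 9084 stayed, 1233 moved and 22 reversed, none of them on leaving out a library. RLE factors moved all genes by 0.01 (log2) in the primed capture. The DESeq2, glmTreat, fry, camera, replicate number and permutation alternatives and the doublet filter were not run. No paired analysis was possible because the numbers of the libraries pair no cultures and each group is 1 capture. Leaving out a library changes depth, not the cells, so it says nothing about replication.

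Gene counts followed the filter by its construction. Without it, genes higher and lower numbered 10812 and 8674 in primed, 5670 and 3642 in luminal-like and 10771 and 9464 in VIM-high cells, and at a mean CPM of at least 10 they numbered 1525 and 1522, 451 and 468, and 1730 and 1806. The goblet cell median in primed cells was 0.35 without the filter. The S phase difference of -10.4 points was -8.93 with all deposited barcodes, -7.30 with the MAD call and -13.3 to -9.48 on leave-one-out. The G2 and M difference of 13.4 was 15.9 unthinned, 2.99 with the MAD call and 14.04 to 16.9 on leave-one-out. The share of parental cells above the score bound was 1.22% at the 1st and 0% at the 10th percentile. The luminal-like share was 15.6% at resolution 0.3, where no mixed cluster formed.

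Sign changes were read as reversals for genes whose interval excluded 0 and lists outside the central 95% of random lists. Besides the goblet cell median, all were in luminal-like over parental cells. In G1 cells only they were MKI67 0.75, TOP2A 0.64 and the G2 and M list 0.048. With the stricter cell filter on the parental side they were CCND1 0.057, LBR -0.16 and MT-CYB 0.57. At resolution 0.3 they were CCND1 0.47, GATA3 -0.29, HLA-C 0.043, LAMA3 -0.0047, MYC 0.30, SEC61B 0.20 and the mitochondrially encoded list -0.12. With the side group as reference they were CCND1 0.061 and GATA3 -0.066. At a mean CPM of at least 10 they were basal epithelium -0.18 and hypoxia and glycolysis -0.024. With free RNA subtracted they were AXL -3.83, ZEB1 -1.81, basal epithelium -0.14 and hypoxia and glycolysis -0.046. Among other list medians, within the central 95%, 43 alternatives changed sign too, as did 3 of a gene whose interval held 0. In luminal-like cells these lists included luminal identity (-0.17), S phase (0.013) and p53 targets (0.016) with the side group as reference, and YAP and TEAD targets (-0.066 with free RNA subtracted). Except where the construction is named, the cause was not tested.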

Other observations

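The tests, genes and groups of cells in this part were all chosen after the data were seen. Neighbouring genes on the short arm of chromosome 12 were nearly silent in luminal-like primed cells, and CLEC2A, TMEM52B and OLR1 in VIM-high cells too. CLEC2B, a lectin-like receptor (positions 9852984 to 9870136 in hg38), stood at 217 CPM in parental and 1.05 CPM in luminal-like cells, OLR1, a receptor for oxidized lipoprotein, at 55.6 and 0.135 CPM, and TMEM52B at 77.1 and 0.216 CPM. CLEC2A stood at 76.3 CPM and at a count of 0, which is 941-fold lower with the 0 set to the floor of 3 counts over the group. The interval of its log2 ratio reached up to -7.58. In VIM-high cells CLEC2A stood at 0.00387, TMEM52B at 0.131, OLR1 at 0.576 and CLEC2B at 19.5 CPM. The parental side group stood between parental and luminal-like cells, with CLEC2B at 51.4, CLEC2A at 18.2, OLR1 at 21.6 and TMEM52B at 37.6 CPM. The neighbours CLEC2D (3.04 and 2.27 CPM) and GABARAPL1 (4.16 and 2.95 CPM) differed by under 2-fold between parental and luminal-like cells, while KLRK1-AS1 and MAGOHB beyond them stood at 12.4 and 47.99% of the parental level.

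Several genes were higher in luminal-like cells than in both parental and VIM-high cells, among them the transcription factor genes TWIST1, TFAP2B and ELF3. TWIST1 stood at 10.9 CPM in parental, 137 CPM in luminal-like and 0.854 CPM in VIM-high cells, TFAP2B at 0.112, 11.3 and 0.0657 CPM, and ELF3 at 11.1, 52.2 and 2.45 CPM. The metalloreductase STEAP4 stood at 0.346, 19.0 and 0.445 CPM, and the antiproliferative gene BTG2 at 3.61, 29.4 and 0.626 CPM.

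Both the parental side group and the luminal-like primed cells had shifts on chromosomes 12, 14, 15 and 20. The side group was picked by its balance of these, so they cannot show whether the sets share a chromosome number change; without them, and against separate parts of the other parental cells, the medians over 19 chromosomes correlated at 0.276, and 8 versions (over chromosomes or windows of 50 genes, with or without chromosomes 5 and 3) ranged from 0.129 to 0.680, which leaves it open. On proximal 3q both sets were higher (windows at 0.25 to 0.30 in luminal-like and 0.40 to 0.42 in side group cells), and they differed, among other places, on chromosome 5 (median -0.42 in luminal-like and 0.02 in side group cells), on 17q from 65010715 to 80119879 (windows at -0.50 and -0.39 in luminal-like cells, -0.08 to 0.03 in the side group) and on distal 3q (windows at 0.19 to 0.29 in the side group, -0.11 to 0.06 in luminal-like cells), and the end of 4p stood at -0.53 and distal 16q at -0.40 in luminal-like cells, against -0.0024 and -0.03 in the side group. The chromosome 15 shift was in VIM-high cells too (-0.45, against -0.51 in luminal-like and -0.44 in side group cells). The chromosome 15 median of the side group was -0.54 in thinned G1 cells and -0.45 in all cells. For these G1 cells this argues against a difference in depth or cell cycle phase. In cluster 4 86.7% of the cells were in G1, but in cluster 3 only 2.57%, so for most of cluster 3 it stays untested. Chromosome 15 also helped to pick the side group, and no DNA was measured.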
